A study of Mus musculus with 12 samples.

How the data were processed

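MC3T3-E1 is a clonal line of osteoblast-like cells from mouse calvaria. Total RNA of 12 samples was measured, 6 from cells kept static (control) and 6 from cells under pulsatile fluid flow (shear). Per the labels' protocols, confluent monolayers on glass slides were grown in medium with 5% serum and placed in a parallel plate chamber. Flow was set to an average shear stress of 5 dyn per square centimetre for 5 h at 1 Hz, in medium with 1% serum. The controls were kept static in the same apparatus. The labels do not say that the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

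Per the labels, RNA was copied into cDNA labelled with Cy5 or Cy3, and 6 spotted 2-colour arrays each took 2 samples of the same condition. Replicates with odd numbers carried Cy5 and those with even numbers Cy3. Replicates 1 and 2, 3 and 4, and 5 and 6 of a group were taken to share an array, an inference from the design and the dyes. Pearson correlations over features were 0.954 to 0.981 within these pairs and 0.873 to 0.915 between other samples of the same group.

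The deposited values are log2 values, 1 per feature and sample, made by the authors. Each value was found to be the log2 of a whole-number net fluorescence divided by its median over a block of 598 features. There were 48 such blocks. With 1 scale per block and sample, 100% of the values came out whole within 0.002, in 576 of 576 combinations of block and sample, which settles the log base. The scanner, the background correction and the rule by which spots were left without a value are not given in the sources used here. Each sample is therefore relative to its own block medians, and a shift common to all genes cannot be seen.

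The deposited file held 28704 features, of which 17080 had a value in all 12 samples and 3206 in none. Between 18434 (control 4) and 23790 (control 1) features had a value per sample. The median net fluorescence per sample ranged from 239.75 (shear 5) to 883 (shear 6). The number of arrays limits the precision. The annotation gave 1 gene symbol for 18511 probes, several for 937 and none for 9256. Symbols of 18267 of the first were updated through the Entrez number, which gave 10225 genes on the array. Probes with several symbols were not named.

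The analysis used R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8), with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Each sample was centred on its median, which moved nothing because the values already had a median of 0. Each gene was represented by the probe measured in most samples, then by the one with the highest mean, and unnamed probes stayed as features of their own. A feature needed a value in at least 4 of 6 samples of each group. This left 15603 features, 8928 of them named genes. limma was fitted with group and dye as fixed terms and the array as a random block. The correlation within arrays was estimated at 0.733, 1 value for all genes. Each array held 1 group, so the groups are compared over 3 arrays each, while the degrees of freedom count the 12 samples. The p-values can therefore be too small. The fit on array means, given below as an alternative, counts arrays only. Changes are shear minus control on the log2 scale with the moderated standard error (SE). P-values were adjusted with the Benjamini-Hochberg method over all features, with a threshold of 0.05.

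The 25 gene lists were tested with camera on the moderated statistics, with a preset correlation between genes of 0.01. They were tested again with a correlation estimated from the residuals, and with fry, which asks whether a list's genes move on balance one way. The lists given by name held 483 entries, many of them not among the genes tested, so a list's result covers its measured members only. Lists with fewer than 5 measured members were given as counts. Adjustment was over the lists. The lists, the tests, the alternatives and the genes to name were chosen before the data were examined, except where said otherwise. The rule named Vegfa first, then the 12 highest and 12 lowest changes among named genes that passed. It added up to 4 members of each list by smallest p, measured members of the VEGF family, and Gapdh, Actb and Gja1 as references. All genes the rule took were carried through every alternative in which they had enough values. Where members of a list missed the threshold, the text gives some as counts or ranges.

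The series is about the gene for vascular endothelial growth factor. No probe was named Vegfa, Vegfb, Vegfc or Vegfd in the annotation used, so the planned comparison of Vegfa was not analysed here.

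The fit was tested on simulated data with the real means, spread, missing values and array correlation of this comparison over 15603 features. Of 100 features changed by 1 on the log2 scale, 20% were recovered, and of 100 changed by 2, 85%. Of 112 calls, 7 were false. In the simulation genes varied independently of one another and all had the same array correlation, as the fit assumes. Real genes are correlated, so this share of false calls need not hold for the real data. The alternatives left out the array block or the dye, averaged each array, changed the scaling, the filters, the probe rule or the threshold, used the replicate number as a block, or left out each sample or array in turn. Centring on the features measured in all 12 samples was added after the data were seen. So were some alternatives of the gene lists.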

Results

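The comparison asked which transcripts differed between MC3T3-E1 osteoblast-like cells after 5 h of pulsatile fluid shear and cells kept static. It rested on 6 samples per group, measured on 6 arrays. In a principal component analysis the first component held 28.6% of the variance and parted the groups. The second held 19.6% and parted the control samples from one another. The array of control replicates 3 and 4 was the weakest, with values for 72.9% and 64.2% of the features.

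**Figure D1:**
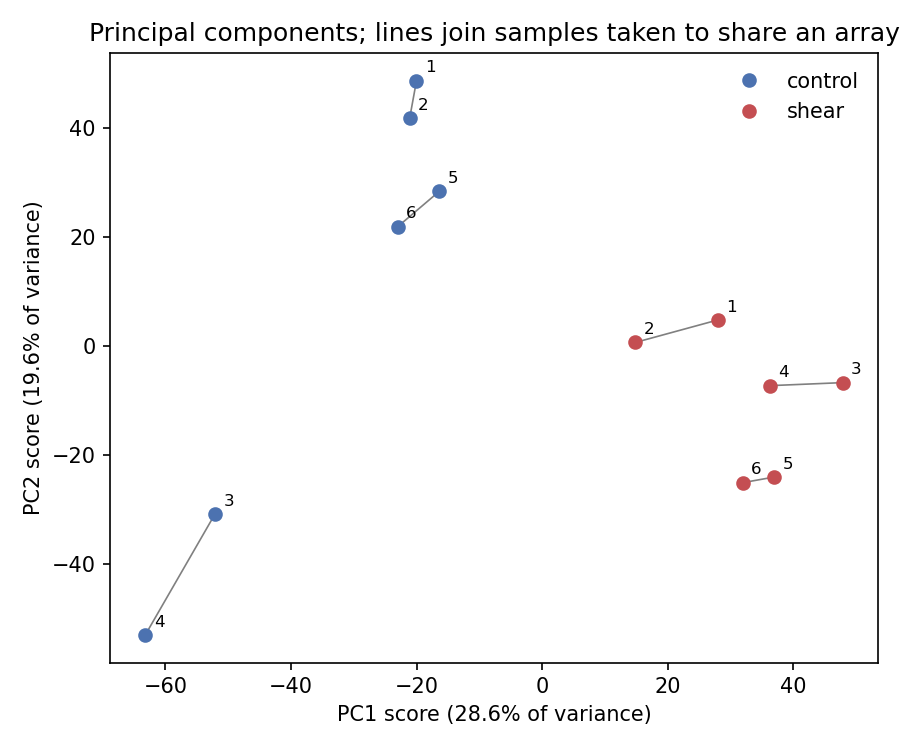
Scores of the 12 samples on principal components 1 and 2 (28.6% and 19.6% of the variance), coloured by group and numbered by replicate, with lines between samples taken to share an array. All shear samples have positive scores on the first component and all control samples negative ones, and control replicates 3 and 4 lie apart from the other controls.

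Among named genes that passed, the highest changes under shear were in genes of several kinds. Hmox1 (Entrez gene 15368), the inducible enzyme that degrades heme, was 20.7-fold higher, a log2 change of 4.37 ± 0.76 (SE, n = 6 per group). Its mean log2 signal was 0.37 ± 0.99 (SD) in control and 4.75 ± 1.25 in shear samples. Nppb, which encodes the precursor of brain natriuretic peptide, was 14.5-fold higher, with a value in 5 control samples. Slc20a1, a sodium-dependent phosphate transporter, was 12.8-fold higher, at 3.67 ± 0.35 (SE) on the log2 scale, and its 2 other probes gave 3.55 each. Sntb2, a syntrophin of the dystrophin complex, was 12.1-fold higher. Limma with Benjamini-Hochberg adjustment gave adjusted p = 0.0116 for Hmox1, 0.00499 for Nppb, 3.14e-04 for Slc20a1 and 0.00101 for Sntb2. The call of Hmox1 was lost in 3 of 32 alternatives.

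The next highest log2 changes of named genes that passed were 3.18 for Fgd6, 2.97 for Gpatch4, 2.83 for Noct (nocturnin), 2.82 for Ier3 and 2.77 for Procr, the protein C receptor. Plaur, the urokinase receptor, rose by 2.74, the AMP deaminase Ampd3 by 2.65 and Zfp36l2, which promotes mRNA decay, by 2.53. The second probe of Fgd6 gave -0.26, so this gene's change rests on 1 probe. Ampd3 had a value in 4 control samples. The other probe of Noct gave 1.33 and did not pass. The call of Ier3 was lost in 15 of 32 alternatives, that of Gpatch4 in 5, that of Procr in 3 and that of Noct in 1.

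Among named genes that passed, the lowest change was that of Col5a3, a chain of type V collagen, at -2.79 ± 0.39 (SE), which is 6.93-fold lower. Its mean fell from 3.48 ± 0.32 (SD, n = 6) to 0.69 ± 0.78 (n = 6), with adjusted p = 0.00326 (limma, Benjamini-Hochberg). Atp5c1, the gamma subunit of the mitochondrial ATP synthase, followed at -2.69, then the glypican Gpc1 and the ubiquitin ligase Lrsam1 at -2.41 each. The log2 changes of Ypel2 (-1.97), Trim47 (-1.93), the sestrin Sesn1 (-1.54), Rpap1 (-1.42) and the uncharacterised AI132189 (-1.38) also passed. So did those of the Polycomb protein Cbx6 (-1.37), Zcchc24 (-1.36) and the phosphatase Ctdsp2 (-1.24). With each array averaged, 9 of these 12 calls were lost, all but those of Col5a3, Trim47 and Sesn1. Over 32 alternatives the call of Gpc1 was lost in 20, that of Cbx6 in 17, Ctdsp2 in 15, Sesn1 in 9, Zcchc24 in 7, Atp5c1 and AI132189 in 4 each and Lrsam1 in 2. That of Ypel2 was lost in 13 of 28 and that of Rpap1 in 6 of 26. The other probe of Gpc1 gave 0.04. Of the 2 other probes of Sesn1, 1 had the sign of the chosen probe and 1 gave 1.93.

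**Figure D2:**
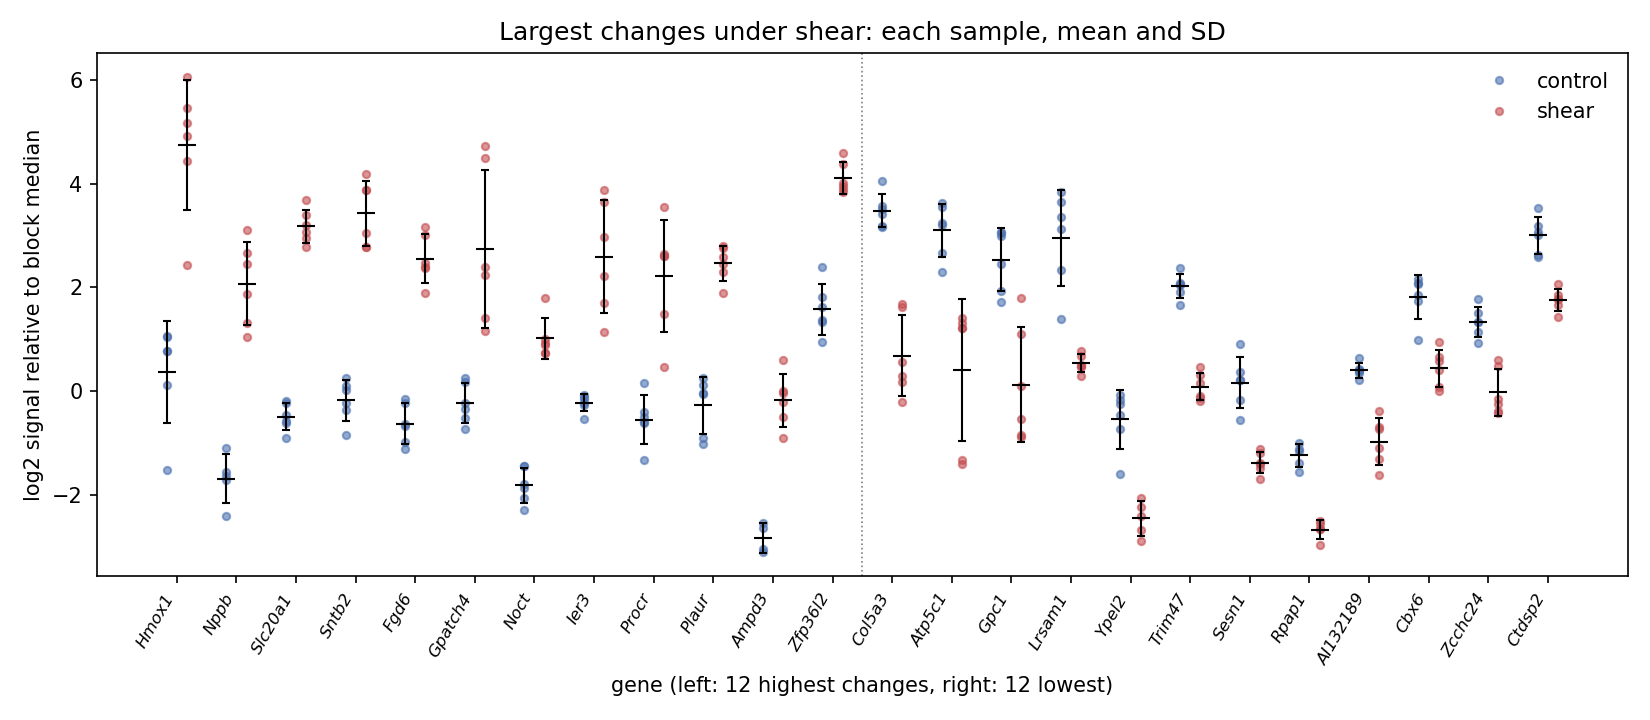
Log2 signal relative to the block median (vertical axis) of the 12 genes with the highest and the 12 with the lowest change among named genes that passed. There is 1 point per sample with a value, blue for control and red for shear, and bars for the mean and SD. Hmox1 goes from a mean of 0.37 to 4.75 and Col5a3 from 3.48 to 0.69.

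In all, 235 features passed, 203 higher and 32 lower under shear, or 86.4% higher. Of these, 159 were named genes, 142 higher and 17 lower. The median change over all features was 0.11 on the log2 scale. With samples centred on the features measured in all of them, that median was -0.02 and the calls were 167 higher and 80 lower (67.6% higher), and with cyclic loess they were 165 and 74. The count fell to 128, 93, 156 and 153 without control replicate 1, 3, 5 or 6 and to 116, 139 and 127 without shear replicate 1, 3 or 6. It was 74 with each array averaged, which counts 3 arrays per group instead of 6 samples. With 1 array left out it was between 42 (without shear replicates 3 and 4) and 169 (without shear replicates 1 and 2).

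Of the vascular endothelial growth factor family, Pgf (placental growth factor) was measured, with a log2 change of 0.02 ± 0.28 (SE, n = 6 per group) that did not pass and turned negative under other scalings, at -0.03 with cyclic loess. Its mean log2 signal was -2.57 in control and -2.55 in shear samples. The 5th percentiles of the samples were -2.87 to -2.18, so Pgf lay near the lowest measured signals and a change could have been missed. Of the 8 measured members of the VEGF and angiogenesis list, none passed over all genes. Angptl4 (1.31) passed when adjusted over the list alone. Efnb2 (1.13), the receptor Flt1 (1.09) and the co-receptor Nrp1 (0.56) did not. The list test gave adjusted p = 0.172 (limma's camera, Benjamini-Hochberg).

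Immediate early genes rose as a list. Of 15 measured members, 3 rose over all genes, namely Ier3, Myc (1.85 ± 0.28 SE) and Ier5 (1.61), and none fell. The call of Ier5 was lost in 18 of 32 alternatives. Adjusted over the list alone, 7 rose, among them Klf6 (1.62) and Jun (1.00). The median was 1.01, and camera gave adjusted p = 5.98e-07 (limma, Benjamini-Hochberg). The call was lost with adjusted p = 0.203 with an estimated correlation.

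Genes of cholesterol synthesis rose as a list, with 3 of 10 measured members higher and none lower. These were Cyp51 (1.59 ± 0.26 SE), Msmo1 (1.42) and Sqle (1.26), enzymes of the late steps of the pathway. Idi1 (1.30) also passed when adjusted over the list alone. The other probe of Msmo1 gave -0.04. The call of Msmo1 was lost in 15 of 32 alternatives, that of Sqle in 4 and that of Cyp51 in 1. Camera gave adjusted p = 1.45e-04 (limma, Benjamini-Hochberg), and adjusted p = 0.0933 with an estimated correlation.

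The list of heat shock and the unfolded protein response rose too, with adjusted p = 0.00112 (limma's camera, Benjamini-Hochberg), and alone among the lists it held with an estimated correlation (adjusted p = 0.0219). None of its 21 members passed over all genes, and 6 rose when adjusted over the list alone. Among these were the chaperones Hspa4 (1.16), Hspa9 (0.84) and Hspa5 (0.78), and Xbp1 (1.08), a transcription factor of the unfolded protein response. The list median was 0.53.

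Of 40 proteasome genes, 2 rose over all genes, Psmd11 (1.40 ± 0.23 SE) and Psmd6 (1.17). Adjusted over the list alone, 6 rose, with Psmd14 (1.03) and Psmd12 (0.99) among them. The call of Psmd6 was lost in 19 of 32 alternatives and that of Psmd11 in 2. The other probes of Psmd11 gave -0.26 and 1.00, and without control replicates 3 and 4 the gene was at -0.71, on another probe. Camera gave adjusted p = 0.00927 (limma, Benjamini-Hochberg), and adjusted p = 0.379 with an estimated correlation. Among 6 measured genes of inflammation and NF-kB, Csf1, the macrophage colony-stimulating factor, rose by 2.18 ± 0.35 (SE). Nfkbia (1.05), Lif (0.93), Mmp9 (0.52) and the 2 other measured members did not pass, and members such as Il6 and Ccl2 were not tested. The call of Csf1 was lost in 1 of 32 alternatives. Camera gave adjusted p = 0.0323 (limma, Benjamini-Hochberg), and adjusted p = 0.0933 with an estimated correlation.

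None of 23 focal adhesion and actin genes passed over all genes on the probe chosen for it. Adjusted over the list alone 2 rose, Itga5 (1.54) and Vcl (1.33), while Tpm1 (0.75) and Actn1 (0.74) did not. With every probe tested, another probe of Vcl passed higher (its 2 other probes gave 0.36 and 1.62). Camera gave adjusted p = 0.0407 (limma, Benjamini-Hochberg), and adjusted p = 0.386 with an estimated correlation. With quantile normalization the calls of the focal adhesion, inflammation and proteasome lists were lost, at adjusted p = 0.157, 0.0641 and 0.178 (limma's camera, Benjamini-Hochberg), and with cyclic loess they were lost as well. Of the 6 settings that left out an array, 3 ended the call of the focal adhesion list, 3 that of inflammation and 2 that of the proteasome.

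The fry test of movement on balance one way used only members with a value in all 12 samples, which left Lif, for example, out of the inflammation list. It passed for the heat shock, cholesterol, proteasome and inflammation lists, with adjusted p = 0.00227, 0.0149, 0.0329 and 0.0329 (limma, Benjamini-Hochberg). It did not pass for the immediate early genes (adjusted p = 0.0566) or the focal adhesion genes (0.0596). It passed for the list of oxidative stress (adjusted p = 0.0329), which camera did not call.

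In the following lists single members passed while camera did not call the list. Of 13 YAP and TAZ targets, Ccn1 (2.47 ± 0.48 SE) and Nuak2 (1.57) rose, with F3 at 1.77 and Crim1 at 0.81 not passing, and the call of Ccn1 was lost in 6 of 32 alternatives. Of 23 glycolysis and hypoxia genes the glucose transporter Slc2a1 rose by 2.08 (lost in 1 alternative), with Pfkfb3 (0.84), Aldoc (0.81) and Bnip3l (-0.63) not passing. Of 8 genes of oxidative stress, Hmox1 rose over all genes and Gclm (1.23) over the list alone, with Mt2 (0.90) and Mt1 (0.52) passing neither. Cycs, which encodes cytochrome c, rose by 1.28 among 15 apoptosis genes, and Mcl1 (1.16) and Bad (0.78) passed over the list alone. Another probe of Mcl1 passed higher with every probe tested, and the other probe of Bad gave -0.27. Casp9 was at -0.63, and the call of Cycs was lost in 17 of 32 alternatives. Camera gave these 4 lists adjusted p = 0.106, 0.248, 0.0999 and 0.981 (limma, Benjamini-Hochberg). The YAP and TAZ and the oxidative stress lists passed camera with each array averaged (adjusted p = 0.00873 each), without the array block (0.0350 and 0.0396), and each with 1 of the 6 arrays left out.

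Of the osteoblast list 10 genes were measured, with 1 that passed in each direction. Other members, such as Runx2, Sp7 and Ibsp, were not among the genes tested. Lox, the enzyme that crosslinks collagen, rose by 2.10 ± 0.41 (SE), a call lost in 4 of 32 alternatives, and Dlx5, a transcription factor of osteoblasts, fell by 0.97 on the log2 scale, a call lost in 23. Msx2 (-0.56) and Serpinh1 (0.23) did not pass. None of the 5 measured bone mechanotransduction genes passed, with values from -0.49 (Igf1) through -0.15 (Igf2), 0.17 (Ptger2) and 0.38 (Ptger4) to 0.52 (Piezo1). Other members of that list, such as Ptgs2, Spp1 and Sost, were not tested. Of 66 oxidative phosphorylation genes, Atp5c1 fell, and Cox5b (1.44), Atp5l (0.83) and Ndufv1 (-0.74) did not pass. Camera gave adjusted p = 0.582 for the osteoblast list (limma, Benjamini-Hochberg), whose median was 0.05 although the test pointed lower.

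On the chosen probes, no member passed over all genes in the lists of the cell cycle (28 measured), cytosolic ribosomal proteins (63), Wnt signalling (13), TGF-beta and BMP signalling (16), calcium and purinergic signalling (13) or gap junctions (11). With every probe tested, another probe of Cav1 (other probes 0.57 and 1.60) and another of Prkcd (other probes from -0.03 to 1.18) passed higher. In the cell cycle list Cdkn1a was at 1.11, Pcna at 0.92, Cdc20 at -0.78 and Mki67 at -0.81. Among ribosomal proteins Rpl10l (1.23) and Rps13 (1.04) lay above 0 and Rpl6 (-0.91) and Rpl13 (-2.02) below it, but the other probe of Rpl6 gave 1.53. Of the calcium list, Atp2a2 (1.34), Prkcd (0.99) and Atp2b1 (0.69) passed over the list alone, and Itpr2 (-0.53) did not. The TGF-beta and BMP genes with the smallest p lay at 0.58 (Smad2), 0.68 (Ltbp1), 0.71 (Smad1) and 0.73 (Bmpr2), with the other members as low as -0.36, and the Wnt genes from -0.64 (Lef1) through Gsk3b (-0.35) and Dkk3 (-0.23) to 0.43 (Axin1). Among the gap junction genes F11r, Cdh2, Cav1 and Jup lay at 0.26, 0.29, 0.29 and 0.30, and the others between -0.20 and 0.12.

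Markers of other cell types did not pass. Those of macrophages and osteoclasts ranged from -0.68 (Lyz2) to 0.34 (Fcer1g), with Tyrobp at 0.28 and Cd68 at 0.29. Of the 6 endothelial markers, Cdh5, Cldn5, Esam and Eng lay at 0.31, 0.40, 0.44 and 0.80, and Tek and Emcn, outside the naming rule, at -0.14 and -0.31. The other probe of Eng gave -0.39. The 4 adipocyte markers were Retn (-0.36), Pparg (0.16), Dgat2 (0.17) and Cidec (0.42). The 4 chondrocyte markers were Col11a1 (-0.35), Col9a1 (-0.20), Col2a1 (0.23) and Comp (0.32), and the 4 muscle markers Tnnt1 (-0.59), Myh3 (-0.17), Cnn1 (0.01) and Mylpf (0.01). The references Gapdh (-0.26 ± 0.36 SE), Actb (0.53 ± 0.36) and Gja1, the main gap junction protein of osteoblasts (-0.06 ± 0.30), did not pass either. Gapdh and Gja1 turned positive without control replicates 3 and 4, at 0.05 and 0.10.

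**Figure D3:**
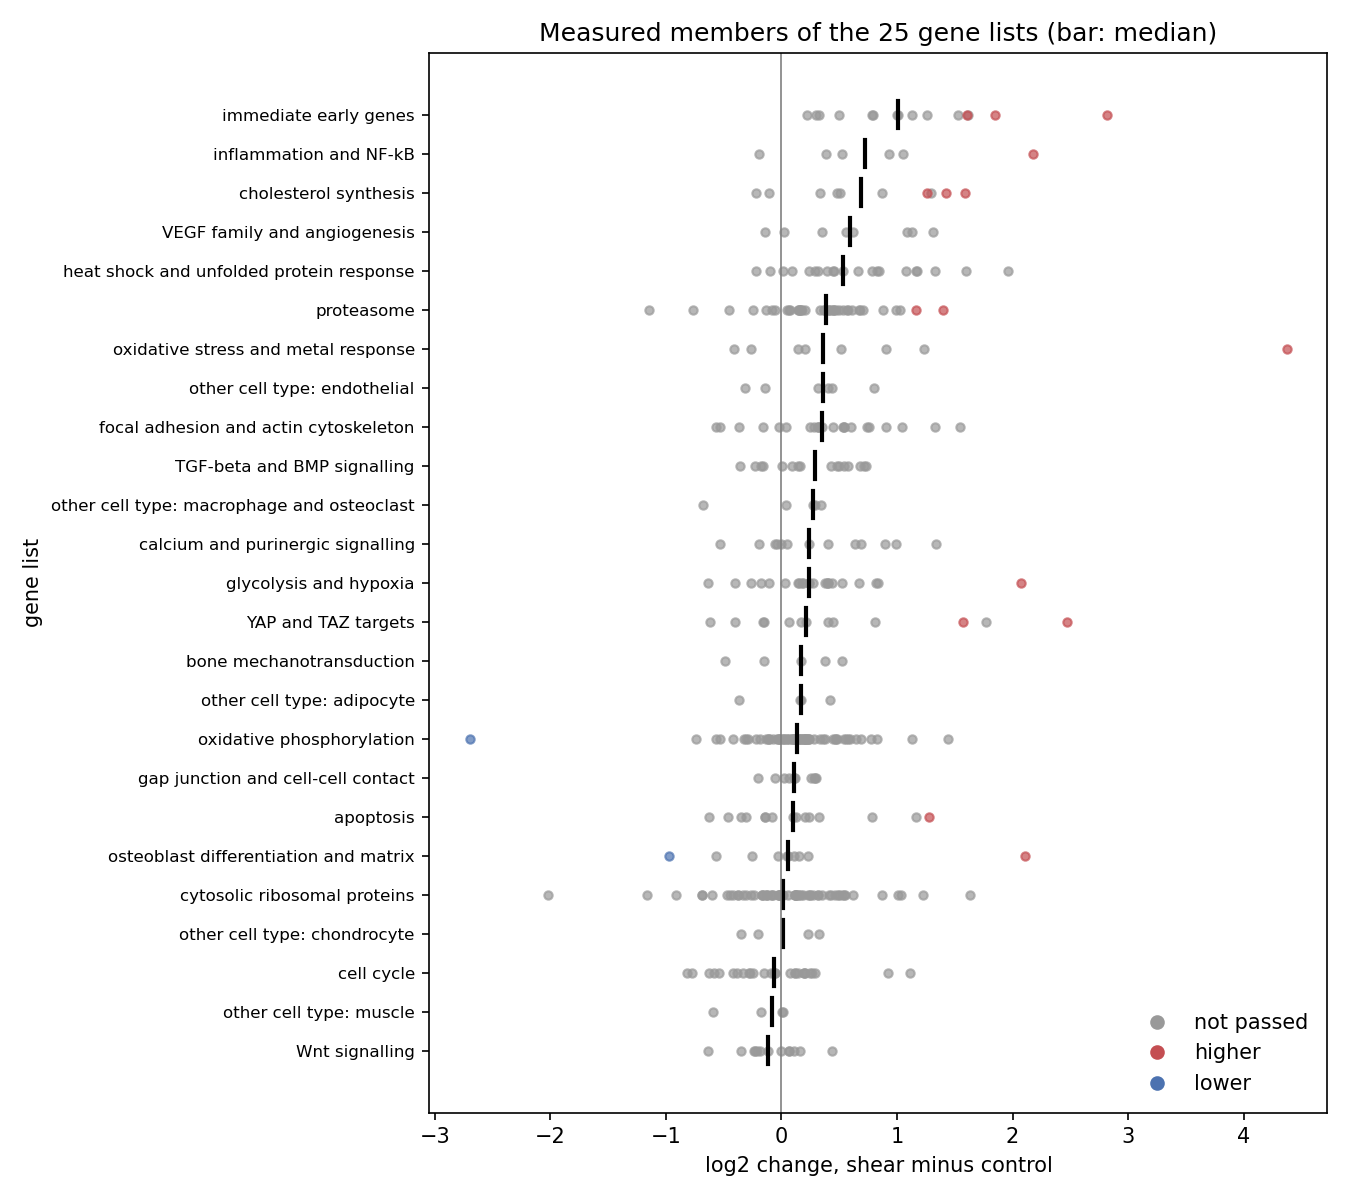
Log2 change, shear minus control (horizontal axis), of every measured member of the 25 lists, ordered by the list median (black bar), in red for genes that passed higher, blue for those that passed lower and grey for the others. The immediate early list has the highest median, 1.01, and Hmox1 the highest single change, 4.37.

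Unnamed features were among those with the smallest p. Probe 20817 fell by 3.90 on the log2 scale, with the lowest adjusted p of all, 6.12e-05 (limma, Benjamini-Hochberg), and probe 12272 by 2.40. Probes 22213 (3.03) and 11170 (1.57) rose. Of the 82 called genes with another measured probe, 73 had at least 1 with a change of the same sign, and 108 of the 128 other probes had that sign. The share due to chance was not worked out. Over the 4049 genes with at least 2 measured probes, called or not, the changes of the first 2 probes correlated at 0.42 (Pearson), so probes of a gene often differed. Among genes that did not pass, a probe of the opposite sign was found also for Atp5l (-0.45), Fcer1g (-0.54), Actb (-0.31), Actn1 (-0.12), Cdh2 (-0.77), Bnip3l (0.23) and Gsk3b (0.31), and among those that passed for Ier5 (-0.09). Except for Atp5l, each of these also had another probe with the sign of the chosen one.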

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

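The tests in this part were chosen after the results were seen. Of 256 groups of samples tested for 1 sample far from the rest (6 per group where all were measured), 13 had one. Chance gives about 1 in 20 for independent samples, but samples of the same array are correlated, so this rate need not hold here. The ratios below are the gap to the nearest sample over the whole range. Shear replicate 2 had the fewest measured features of its group, 21847 (ratio 0.636).

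In control replicate 4 Hmox1 was at -1.52 against 0.13 in the next sample (ratio 0.638), and Sqle (1.81, ratio 0.765), Xbp1 (0.83, ratio 0.752) and Cbx6 (0.99, ratio 0.643) were also the lowest of their group. Ier5 was lowest in control replicate 3 (0.23, ratio 0.630) and Ptger4 in control replicate 6 (0.64, ratio 0.799). In shear replicate 2, Slc2a1 was low (2.15, ratio 0.732), while Nfkbia (1.93, ratio 0.753) and Mylpf (-1.72, ratio 0.634) were high. Noct was high in shear replicate 3 (1.80, ratio 0.752), Lif was low in shear replicate 5 (0.35, ratio 0.630) and Comp was low in shear replicate 1 (-0.31, ratio 0.631).

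Outside the comparison, 43 features had a value in all 6 shear samples and in no control sample, against 7 the other way. They included Hbegf, a growth factor of the EGF family, at a mean log2 signal of 2.39 ± 0.45 (SD, n = 6), named after its values were seen. For 1 such gene, Igf2, the feature was 1 of its probes, at 0.31 ± 0.73, while the probe measured in both groups had a log2 change of -0.15 and did not pass. Of the 43, 76.7% had a shear mean above -2.18, the highest 5th percentile of measured values among the control samples. The 5th percentiles of the shear samples were -2.87 to -2.30, so most features measured under shear lie above that level in any case. The share therefore cannot decide whether a higher detection floor in the controls was the cause. Another split of the 6 arrays into 3 and 3, which joined the controls of replicates 1, 2, 5 and 6 with shear replicates 1 and 2, gave 51 such features, so 2 of the 10 splits gave as many. That split sets the weak array of control replicates 3 and 4 among the other arrays, and with 10 splits chance and shear cannot be told apart for these features.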

How the results depend on the processing

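The 1.5-fold limit and leaving out the median centring, which moves nothing, both gave 235 calls. The count was 1717 (1270 higher, 447 lower) without the array block, 74 (69, 5) with array means, 360 (306, 54) without the dye and 129 (111, 18) with quantile normalization. It was 362 (317 higher) with every probe tested. Fewer features were lower without the dimmest features (18), and more with cyclic loess (74) or with centring on the features measured in all samples (80), which was chosen after seeing the data. Leaving out 1 sample gave 93 to 251 calls, 84 to 217 higher and 9 to 47 lower. Leaving out the array of control replicates 1 and 2, 3 and 4, or 5 and 6 gave 137 (128 higher, 9 lower), 127 (90 higher) and 84 (72, 12). Leaving out that of shear replicates 3 and 4 or 5 and 6 gave 42 (37, 5) and 76 (63, 13). A fit without the array block takes samples of the same array as independent although they are correlated (0.733), so its p-values are too small. Array means leave 3 values per group. The cause of the other differences was not tested, and where samples were left out the fits also had fewer of them.

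With the replicate number as a block, and no array block, 1452 features passed (1096 higher, 356 lower). The values gave no sign that the numbers pair the samples: deviations of same-numbered samples correlated at -0.14 to 0.09, and 1 of 6 numbers correlated best with itself. These deviations still hold the differences between arrays, so a weaker pairing could be hidden. The number of lists that passed, 6, was 1 with the estimated correlation, 3 with quantile normalization and 3 with cyclic loess, and 4 to 8 otherwise. The planned comparison of Vegfa was not run, for want of a named probe.

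Of the 38 named genes that passed, Ampd3, Col5a3, Fgd6, Myc, Nppb, Nuak2, Plaur, Slc20a1, Sntb2, Trim47 and Zfp36l2 passed in every alternative that measured them. The alternatives counted include the 1.5-fold limit and leaving out the median centring, which could end no call. All 38 calls were also kept in the fits without an array block, whose p-values are too small. Dlx5 was lost in 23 of 32, Gpc1 in 20, Psmd6 in 19, Ier5 in 18 and Cbx6 and Cycs in 17. Psmd11 reversed to -0.71 without the array of control replicates 3 and 4, a setting that can choose another probe. Genes that had not passed reversed as follows. Without that array, Eng was -0.39, Jup -0.14, Cd68 -0.035, Col2a1 -0.15, Pgf -0.31, Cnn1 -0.28, Gja1 0.096 and Gapdh 0.047. Without the array of control replicates 1 and 2, Cdh2 was -0.0056 and Myh3 0.11. Without that of shear replicates 1 and 2, Atp5l was -0.063, Pgf -0.0996, Mylpf -0.043 and Myh3 0.19, without 3 and 4, Pparg was -0.060, Cnn1 -0.38 and Gja1 0.11, and without 5 and 6, Pparg was -0.0088, Cnn1 -0.19, Gja1 0.055, Col11a1 0.021 and Gsk3b 0.32. With cyclic loess Pgf was -0.031 and Cnn1 -0.078, and centred on the features measured in all samples Pgf was -0.12, Mylpf -0.025 and Cnn1 -0.13. With 1 sample left out, Cnn1 ranged from -0.089 to 0.082, Eng from -0.39 to 0.90, Pgf from -0.059 to 0.071, Col11a1 from -0.81 to 0.10, Gja1 from -0.14 to 0.020, Atp5l from -0.51 to 0.88 and Mylpf from -0.068 to 0.077. Where samples were left out, the probe of each gene was chosen anew. For Psmd11 and Atp5l the chosen probe was higher in every shear sample than in every control sample, so their reversals come from another probe. The -0.39 of Eng is the value of its other probe. The cause of the other reversals was not tested. Signal over background was not measured. The typical median of a block was 6.24 (control 4) to 18.5 (shear 3) times its typical lowest net fluorescence.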

Other observations

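The tests in this part were chosen after the results were seen, apart from the splits of the samples and arrays. Genes that make ribosomes were gathered by symbol after the results were seen. Of 77 measured members 11 rose over all genes and none fell, 24 rose when adjusted over the family alone, and 89.6% had a change above 0. The highest included Utp18 (2.02 ± 0.31 SE, n = 6 per group), Pno1 (1.62) and Wdr75 (1.59), which process ribosomal RNA, the nucleolar helicase Ddx21 (1.48), and Polr1d (1.35), a subunit shared by RNA polymerases I and III. The 63 cytosolic ribosomal proteins had a median of 0.02, and none passed.

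Other families gathered in the same way passed camera (limma, Benjamini-Hochberg), but not with an estimated correlation. For 40 translation initiation factors, with Eif1a at 1.20, adjusted p = 0.00429, and adjusted p = 0.178 with an estimated correlation. For 24 splicing factors of the SR and hnRNP families, with Hnrnpa3 (1.00) and Srsf2 (0.97) higher, adjusted p = 0.0168, and adjusted p = 0.124 with an estimated correlation. For the 8 subunits of the chaperonin ring adjusted p = 0.00952, and adjusted p = 0.285 with an estimated correlation. Transfer RNA synthetases, nuclear transport factors, mitochondrial ribosomal proteins, collagens, histones, solute carriers and Zfp genes did not pass.

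A hypothesis is that the genes of ribosome production rose together beyond the other genes under shear. With an estimated correlation camera gave adjusted p = 0.0439 over the families (limma, Benjamini-Hochberg). The call held centred on the features measured in all samples (adjusted p = 1.01e-04) and with cyclic loess (0.00190), and was lost with quantile normalization (0.157) and without control replicates 3 and 4 (0.0966). The family's median was 0.61 against 0.11 over all features, 0.47 against 0.09 with quantile normalization and 0.50 against 0.01 without those replicates. A misleading choice of probe is argued against, since the 76 other probes of the family had a median change of 0.69. The family may still have been picked out by chance, as it was found and tested on the same data.

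Of 100 splits of the 12 samples drawn, the real one included, 1 gave as many calls as the real 235, and the highest other gave 5. Of these splits 98 parted samples of the same array, which are correlated (0.733), so the share excludes chance only if the samples are taken as independent. With arrays kept whole, 1 of 10 splits gave as many, and the highest other gave 12. The 10 splits are too few for a share under 0.05.

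More features were called higher than lower, 86.4% against 67.6% with samples centred on the features measured in all of them, so the excess depends on the scaling. Under that centring the share was 58.2% or more whichever array was left out, but its jackknife SE over arrays was 17.4 percentage points, so it does not lie clear of an even share. Without the weak array of control replicates 3 and 4 the share was 70.9% (jackknife SE 10.1 percentage points), and 59.7% with shear replicates 1 and 2 left out too. Under the centring on features measured in all samples it was 64.8% without the weak array. With so few arrays the SE is itself uncertain, so the weak array alone is not excluded as the cause. What stays open is a response to flow, the scaling on each sample's own median, the weak array, and any difference between the arrays of the 2 groups, since each array held 1 group.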
